A study of Clostridium drakei with 4 samples.

How the data were processed

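RNA sequencing libraries, 4 in all, were made from cells of Clostridium drakei SL1T, an anaerobic, acetate-forming bacterium that can live on sugars or on H2 and CO2. Per the labels' protocols, 2 libraries came from cells grown on fructose (5 g/L) and 2 from cells grown on a gas phase of 80% H2 and 20% CO2 at 200 kPa. Cells grew at 30 °C without oxygen from a starting optical density near 0.05 and were collected in mid-exponential phase. The medium of both conditions also held yeast extract. Ribosomal RNA was removed with a bacterial depletion kit, and strand-marking libraries were sequenced as 150 bp reads on a MiSeq, per the labels' protocols.

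The authors deposited 1 table of counts, with a row for each of 5004 locus tags and a column for each library. Its values are whole numbers whose column totals differ between libraries, so they were treated as raw counts that had not been scaled. Per the submitters' processing notes, DESeq2 was used, with no version or role stated. The aligner, the counting program, the strand setting, the genome build and the annotation are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies can therefore not be told apart from those of the gene they are listed under. The table and its headers pair no gene name or product with the locus tags, and no annotation was used here. The 27 gene lists fixed before the data were examined (the Wood-Ljungdahl pathway, the glycine synthase-reductase pathway, hydrogenases, ribosomal proteins and others) were defined by product names. They could not be matched to any row, so 0 lists were tested. All table columns belonged to a library (0 columns of no sample). Columns were assigned to libraries by the sample titles, which hold the column names.

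The count totals were 5234542 and 4661775 for the fructose libraries and 3003842 and 1511487 for the H2/CO2 libraries. A count of 3, the upper limit that a count of 0 allows, equals 0.515 and 0.599 normalized CPM in the fructose libraries. In the H2/CO2 libraries it equals 0.998 and 2.38. Limits and intervals of this kind cover the counting error of reads only and leave out the spread between libraries. The reads carry no molecular identifiers, so copies of the same molecule would be counted as separate reads. The labels call the libraries of a group replicates of a cell culture without saying whether the cultures were separate, so p-values measure the spread between these libraries, which may be partly technical. The libraries of each pair were checked for being 1 library deposited more than once. Their counts differed by more than sampling noise in both pairs, with a chi-square statistic of 12.5 per degree of freedom for fructose and 21.5 for H2/CO2 over genes with a summed count of at least 10.

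The comparison, fixed before the data were examined, was H2/CO2 minus fructose, with all 4 libraries in the fit and no covariate. It used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors and genes kept by filterByExpr (minimum count 10), which left 3981 genes. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are described as having risen or fallen. Standard errors (SE) of log2 fold changes were computed as the log2 fold change divided by the square root of the test statistic. Where a group has few counts, this value can be smaller than counting error allows and does not measure precision. Normalized CPM are counts divided by the TMM-scaled library size and multiplied by 1e6. Normalized counts are scaled to the mean of those sizes. Log2 values between single libraries used an offset of 0.5 counts. The smallest two-sided p that a permutation of 2 against 2 libraries can give is 0.333, so no permutation test of single genes was made.

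Genes to be named were chosen by a rule fixed before the data were examined, in the form it takes without gene names. These are the 2 genes with the largest rise and the 2 with the largest fall among genes past the threshold, with both libraries of one group above both of the other and a mean normalized count of at least 50. Folds of these genes are also given from summed counts, with exact binomial 95% intervals. Intervals of a run's share of counts in a single library are 95% Wilson intervals.

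Runs of consecutive locus tags were examined as an analysis chosen after the data were seen. Tags in this table are numbered in steps of 5. A run is a stretch of consecutive tag numbers whose genes all passed the threshold in the same direction, and a tag that is untested or outside the table ends it. Locus tags are commonly numbered along the sequence, but positions, strands and operons were not used here. Observed runs were compared with 10000 random orders of the tested genes over the same tags. Block bootstrap intervals resampled stretches of 50 tags with the libraries held fixed, so they leave out the spread between libraries. This part used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

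The gene test was checked on simulated counts drawn for the 3981 genes at these library sizes, with 200 genes changed in the simulated H2/CO2 minus fructose comparison. It recovered 6 of 50 genes changed 1.5-fold, 32 of 50 changed 2-fold, 47 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 6 false calls. With no gene changed it made 0 calls. The simulation drew genes independently, with the same dispersion in both groups. In the data the coefficient of variation beyond counting error was 0.115 for fructose and 0.235 for H2/CO2, and neighbouring tags were correlated. The simulated false calls therefore do not give the error rate of the test in these data. Alternatives were RLE factors, DESeq2 1.42.0, no filter, a mean count of at least 50, a minimum log2 change of 1, the replicate number as a block, and leaving out each library. Scaling by total count, thinning to the smallest total and thinning to equal TMM-scaled library size were added after the data were seen. The labels give no batch or date, and depth differed between the conditions.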

Results

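The transcriptome of Clostridium drakei was measured by RNA sequencing during growth on fructose and during growth on H2/CO2, with 2 libraries of each. The series title places the study around 2 routes of CO2 fixation, the Wood-Ljungdahl pathway and the glycine synthase-reductase pathway. The comparison asks how transcript levels differ when the carbon and energy source is a gas mixture in place of a sugar. Genes are identified by locus tag, because the count table gives no gene names, so neither pathway could be located among the rows. Libraries held between 1511487 and 5234542 counts. The H2/CO2 libraries were the shallower ones, with 2257665 ± 1055254 counts against 4948159 ± 405007 for fructose (SD, n = 2 each).

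The libraries separated by growth condition far more than by replicate. Across the 3981 tested genes, the median absolute log2 difference between the fructose libraries was 0.18, which is a 1.14-fold difference. Between the H2/CO2 libraries it was 0.39, or 1.31-fold. Between libraries of different conditions it lay between 0.78 and 0.79. Pearson's r of log2 values across genes was 0.989 within the fructose pair, 0.960 within the H2/CO2 pair and 0.776 to 0.799 between conditions. Genes are not independent replicates, so these values describe the libraries and carry no p-value. The first principal component separated the conditions and held 88.9% of the variance. The second held 8.55% and separated the H2/CO2 libraries from each other. A count was recorded for 4462 of the 5004 genes in all 4 libraries, and 124 genes had none in any.

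Transcript levels of a large part of the genes differed between the conditions. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1829 of 3981 genes (45.9%) passed the threshold, of which 923 rose and 906 fell on H2/CO2. Both libraries of one condition lay above both of the other in 1828 of these genes. These genes were selected for their difference, so their separation is not a further test. Of all tested genes, the selected ones included, 73.7% were separated in this way, where chance alone gives 33.3%. The median gene that rose did so 3.18-fold, and the median gene that fell did so 2.49-fold. Changes of at least 2-fold were found in 719 genes that rose and 645 that fell. Among larger changes, rises were more frequent: 391 genes rose and 211 fell at least 4-fold, 122 rose and 34 fell at least 16-fold, and 45 rose and 11 fell at least 64-fold. Among the 2152 genes that did not pass, 1433 had a fitted log2 change within 0.5 of 0. The simulated comparison recovered 12% of genes changed 1.5-fold at these depths. It changed only 200 of 3981 genes, so its Benjamini-Hochberg cutoff was stricter than here, where 1829 passed. Its recovery therefore does not carry over to these data, though small changes may still have been missed.

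The balance of rises and falls depended on the scaling. With libraries scaled by total count, 684 genes rose and 1084 fell, and the median log2 fold change of all tested genes was -0.21 in place of 0.03. At least 4-fold changes then numbered 332 rises and 258 falls. Without fructose replicate 1 the number of changed genes was 1186, and without fructose replicate 2 it was 1145. In these fits the lone fructose library was assumed to vary as the H2/CO2 libraries did.

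**Figure D1:**
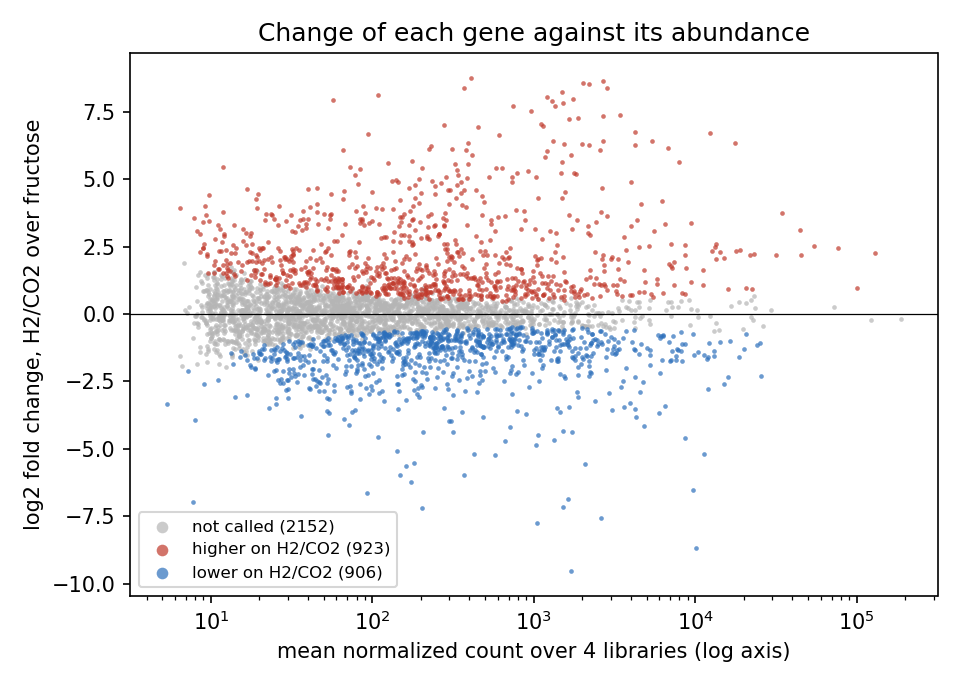
Each point is a tested gene, with its mean normalized count over the 4 libraries on a log x axis and its log2 fold change, H2/CO2 over fructose, on the y axis. Red points are the 923 genes that rose, blue points the 906 that fell and grey points the 2152 that did not pass the threshold. More rises than falls lie far from 0, though the largest change of a named gene is a fall.

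The changes reached the most abundant genes and shifted a large part of the counts. Without gene names, rows of ribosomal or other structural RNA could not be set apart from mRNA. Genes that rose made up 55.3% ± 0.55 of the counts on H2/CO2 and 16.8% ± 0.64 on fructose (SD, n = 2 each). Genes that fell made up 44.7% ± 0.71 of the counts on fructose and 13.0% ± 0.60 on H2/CO2. These genes were selected for their change, so the shares describe its size and are not a further test. Fewer genes passed without a fructose library, and the share of genes that rose on fructose was then 9.58% (without replicate 1) or 9.78% (without replicate 2). The share of genes that fell on H2/CO2 was 7.50% without fructose replicate 2. With a minimum log2 change of 1, these shares were 10.2% and 8.55%. Of the 50 most abundant genes on H2/CO2, 33 had risen and 3 had fallen. Of the 50 most abundant on fructose, 25 fell and 7 rose on H2/CO2, and 24 genes were among the top 50 in both conditions. Each list was ranked by the level in its own condition. That ranking favours rises in the H2/CO2 list and falls in the fructose list, so these counts are not a further test. The 10 most abundant genes took 27.9% ± 1.41 of the counts on H2/CO2 and 19.7% ± 0.24 on fructose, and 5 genes were in both lists of 10. Among 4 classes of genes by abundance, calls were made in 23.7% of the lowest class and in 67.8% of the highest, where counts are larger and the test more precise.

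The largest rises were in the adjacent tags B9W14_09470 and B9W14_09465. B9W14_09470 had 3 and 2 counts in the fructose libraries and 523 and 325 in the H2/CO2 libraries, or 0.457 ± 0.082 and 216 ± 59 normalized CPM (SD, n = 2 each). Its log2 fold change was 8.76, with an edgeR adjusted p of 3.94e-07. The SE from the test statistic, 0.38, understates the error of so few fructose counts. The fold from summed counts was 431, with a 95% interval of 184 to 1329, wider than that SE implies. B9W14_09465 rose from 3.54 ± 0.64 to 1411 ± 524 normalized CPM (SD, n = 2 each), with a log2 fold change of 8.63 (SE 0.39, edgeR adjusted p 4.87e-07) and a summed-count fold of 359 (261 to 508). Both tags belonged to a run of 9 consecutive tags that all rose, by 12.9-fold to 434-fold with a median of 252-fold. The run took 0.687% ± 0.068 of the counts on H2/CO2 and 0.0095% ± 0.0009 on fructose (SD, n = 2 each).

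The largest falls were in B9W14_06785 and B9W14_24785. B9W14_06785 had 5487 and 4264 counts on fructose and 3 and 2 counts on H2/CO2, or 897 ± 64 and 1.29 ± 0.42 normalized CPM (SD, n = 2 each). Its log2 fold change was -9.53, with an edgeR adjusted p of 2.41e-07. The SE from the test statistic, 0.33, understates the error of so few H2/CO2 counts. The summed counts gave a 768-fold lower level, with a 95% interval of 329 to 2367, wider than that SE implies. One neighbouring tag fell with it, in a run of 2. B9W14_24785 was far more abundant on fructose, at 5324 ± 1618 normalized CPM, and stood at 14.0 ± 6.1 on H2/CO2 (SD, n = 2 each). Its log2 fold change was -8.68 (SE 0.45, edgeR adjusted p 9.85e-07), and its summed-count fold was 444 (338 to 594). It was in a run of 3 tags whose median fall was 191-fold. This run held 1.29% ± 0.35 of the counts on fructose and 0.0070% ± 0.0004 on H2/CO2 (SD, n = 2 each). All 4 genes kept their direction and an adjusted p under 0.05 in each of the 12 alternatives that refitted the counts.

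**Figure D2:**
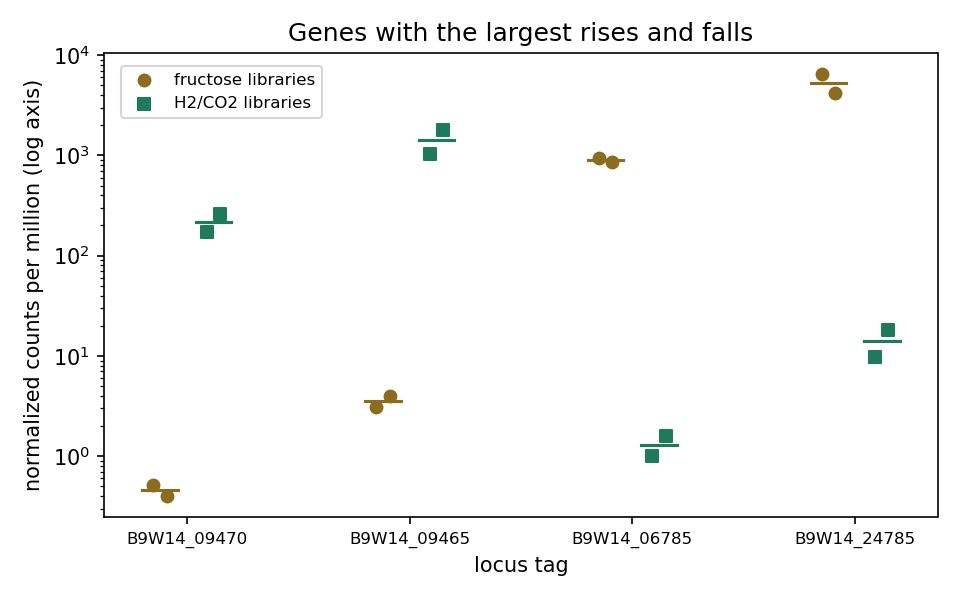
Normalized CPM on a log y axis for the 2 genes with the largest rises and the 2 with the largest falls, with one symbol per library (circles, fructose; squares, H2/CO2) and a bar at the mean of each pair. B9W14_06785 falls from 897 to 1.29 and B9W14_09470 rises from 0.457 to 216, far beyond the distance between paired symbols.

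Genes changed together in stretches of neighbouring tags. Of the 1829 changed genes, 1012 lay in 188 runs of at least 3 consecutive tags with the same direction, and 651 lay in 80 runs of at least 5. Random orders of the genes gave on average 186 and at most 275 genes in runs of 3 or more (permutation test, one-sided p = 0.0001, the smallest that 10000 orders can give). Random orders remove all coupling between neighbours, including that of differences between replicates, so the test addresses chance placement only. The runs of 3 or more comprised 95 that rose with 502 genes and 93 that fell with 510 genes. Among them, 13 runs rose and 3 runs fell by a median of at least 16-fold. Without fructose replicate 1 the genes in runs numbered 642, and without fructose replicate 2 they numbered 636.

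Several long runs held a large part of the counts. A run of 18 tags rose by a median of 4.97-fold, with every member between 3.18-fold and 6.08-fold. It accounted for 13.1% ± 1.49 of all counts on H2/CO2 and 3.08% ± 0.51 on fructose (SD, n = 2 each), the largest share of any run that rose. A run of 5 tags came next, with 6.85% ± 0.74 on H2/CO2 and 1.45% ± 0.32 on fructose. Another run of 18 tags held 0.0157% ± 0.0021 of counts on fructose and 0.400% ± 0.240 on H2/CO2, with a median rise of 29.2-fold. The longest run that fell held 37 tags, which fell between 1.77-fold and 5.77-fold with a median of 2.81-fold. It took 9.51% ± 0.23 of the counts on fructose and 2.86% ± 0.99 on H2/CO2, the largest share of any run that fell. A run of 13 tags fell by a median of 2.06-fold and dropped from 4.52% ± 0.13 to 1.68% ± 0.23 of counts. The strongest fall of a run of at least 5 tags was in 5 tags with a median of 28.9-fold, from 0.247% ± 0.042 to 0.0078% ± 0.0011 of counts. These runs were picked after their values were seen, by length, strength or share of counts.

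**Figure D3:**
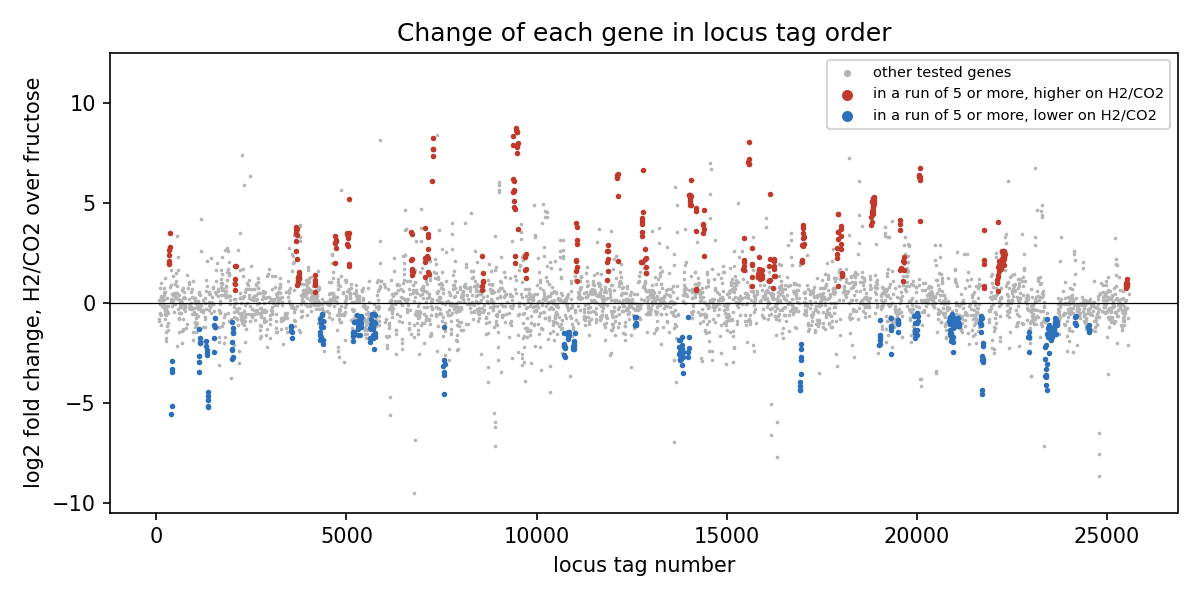
Log2 fold change, H2/CO2 over fructose, of each tested gene on the y axis against its locus tag number on the x axis. Coloured points are the 651 genes in the 80 runs of at least 5 consecutive tags that rose (red) or fell (blue), seen as short vertical stacks spread over the whole range of tags.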

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

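Scaling by total count and both kinds of thinning were chosen after the data were seen, as was the count of genes in runs under every setting; the other alternatives were fixed before the data were examined. The number of changed genes was 1829 as reported and stayed within 1.5 times that value at 1811 with RLE factors, 1478 with DESeq2, 1852 with no filter, 1488 with a mean count of at least 50, 1364 with a minimum log2 change of 1, 1768 with scaling by total count, 1562 with libraries thinned to equal totals and 1476 with libraries thinned to equal TMM-scaled size. With the replicate block it was 1783, of which 1733 were shared with the reported calls, and the block changed no call of a named gene. The labels give the groups the same replicate numbers without saying that they pair the libraries, and the correlation across genes of the log2 difference between replicates 1 and 2 was -0.099 between the groups. Leaving out 1 library gave 1145 to 2211 changed genes and 636 to 1217 genes in runs of at least 3 tags. The low ends came without a fructose library, when the spread was estimated from the H2/CO2 pair alone. No gene called both as reported and under an alternative changed direction. The spread between replicates fell to 0.15 (fructose) and 0.33 (H2/CO2) with a mean count of at least 50, and rose to 0.25 and 0.41 at equal totals and to 0.27 and 0.41 at equal TMM-scaled size. Over the 13 alternatives, genes that rose held 44.2% to 58.7% of H2/CO2 counts and 9.58% to 20.0% of fructose counts, and genes that fell held 7.50% to 18.9% of H2/CO2 counts and 32.7% to 53.6% of fructose counts. The adjusted p of the named genes was at most 4.41e-05 in any alternative. The gene list tests and their alternatives were not run, because no gene names could be matched, and the pseudocount alternatives did not apply to counts. Depth limits the H2/CO2 side: the median tested gene had 34 counts in replicate 2 against 86 in replicate 1 and 147 and 128 in the fructose libraries.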

Other observations

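The pattern of adjacent tags changing together was tested against chance only after it was seen, and the tests of independent noise between genes and of depth at equal TMM-scaled size were also chosen after related values were seen. A first test of independent noise was undecided and was replaced: the correlation of the replicate log2 ratio between adjacent tags of the H2/CO2 pair was 0.18, between the bounds of 0.05 and 0.2 set for it. The other tests were set before their results were seen, except that the interval for genes with a mean normalized count of at least 200 was added afterwards. Runs of tags differed in how close the H2/CO2 libraries lay, as values with no test, since counting intervals leave out the spread between libraries. The run of 18 tags with the smaller share of counts held 0.230% of the counts in replicate 1 (95% Wilson interval 0.225 to 0.236) and 0.569% in replicate 2 (0.557 to 0.581). The 37-tag run that fell held 2.16% (2.14 to 2.18) and 3.56% (3.53 to 3.59). The abundant 18-tag run that rose held 12.1% (12.03 to 12.10) and 14.2% (14.12 to 14.23).

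The H2/CO2 libraries lay further apart than the fructose libraries, with a median absolute log2 difference 2.11 times as large. The ratio was at least 1.58 in 20 thinnings to equal totals, and 1.47 to 1.57 at equal TMM-scaled size. At equal TMM-scaled size it stayed above the 1.1 set for depth alone but did not clear 1.5 in every draw. Thinning adds counting noise to both pairs, which draws the ratio toward 1, so the part due to depth is open. Genes with a mean count of at least 50 had spreads of 0.15 (fructose) and 0.33 (H2/CO2). The coefficient of variation beyond counting error, from edgeR's common dispersion, was 0.115 for fructose and 0.235 for H2/CO2. Admixture of RNA from the other growth condition, as the whole cause, would leave genes with equal levels in both conditions in place. Among 756 genes with a log2 change within 0.25, however, the ratio was 2.52, and 1.52 to 1.75 after thinning to equal TMM-scaled size. Changed genes were left out there, so admixture as a part of the cause stays open. Noise independent between genes, as the whole cause, would add nothing to the covariance of adjacent tags, yet that was 2.46 times as large in the H2/CO2 pair (95% block bootstrap interval 1.37 to 4.61). It stays open for most of the excess, since the variance grew 3.33 times, the adjacent-tag correlation was lower than the 0.25 of the fructose pair, and the added covariance was 0.15 of the added variance; a difference in culture state or handling may also remain and was not tested.

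Neighbouring tags changed together beyond chance placement, with a correlation of log2 fold changes of 0.68 between adjacent tags against at most 0.071 in 10000 random orders. Log2 ratios between replicates also exceeded every random order, at 0.25 in the fructose pair and 0.18 in the H2/CO2 pair. At a distance of 3 tags these were 0.16 and 0.09. Exceeding random orders is therefore not particular to the change of condition. Reads shared by adjacent genes would couple direct neighbours, but the correlation of log2 fold changes was still 0.37 at a distance of 3 tags. At 10 and 20 tags it was 0.088 and 0.096, above every random order (at most 0.068 and 0.072), so a weak coupling reached that far. A gradient along the whole genome would persist over long distances, whereas the correlation at 50 tags was -0.015 times that of adjacent tags. Genes transcribed together as operons or controlled by shared regulators may be the source, a hypothesis that needs gene positions and strands to test.

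Large rises outnumbered large falls, by 391 to 211 genes at 4-fold, or 1.85 rises per fall. Genes with low counts did not account for all of this, since genes with a mean normalized count of at least 200 gave 2.04 rises per fall (95% block bootstrap interval 1.35 to 3.18). Intervals of this kind reflect which stretches of tags were drawn and leave out the spread between libraries. A filter on a mean count of at least 50 lowered the ratio to 1.60 (1.08 to 2.44), so a part played by low counts stays open. With scaling by total count the ratio was 1.29 at 4-fold (0.913 to 1.84). At 4-fold a scaling effect therefore cannot be told apart from a real excess of rises without an external standard. The 4-fold ratio was also lower without H2/CO2 replicate 2, with an interval that included equal numbers of rises and falls. Leaving out any other library kept more rises than falls over the whole interval. The 4-fold excess thus depended on the libraries used as well as on the scaling. At 16-fold the excess remained with scaling by total count, at 2.78 rises per fall (1.37 to 5.56). Scaling by total count moved the median log2 fold change only from 0.03 to -0.21, so a larger scaling difference was not tested.

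The last 19 rows of the table were out of locus tag order. Of the 18 tested among them, 14 had changed (11 rose and 3 fell), or 77.8%, against 45.8% of the 3963 tested genes in order (a comparison chosen after the order was seen). The shares carry no test, since neighbouring genes are not independent and the share of changed genes rose with abundance, from 23.7% in the least abundant 25% of tested genes to 67.8% in the most abundant 25%. A change of at least 16-fold was found in 7 of the 18 genes. No explanation was tested.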
